A study of Clostridium autoethanogenum DSM 10061 with 9 samples.

How the data were processed

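The series holds 9 RNA-seq libraries of *Clostridium autoethanogenum* from 3 culture conditions with 3 libraries each. Per the labels' protocols, each culture held 100 mL of PETC medium at pH 5.5 and was kept without oxygen at 37 °C and a headspace pressure of 200 kPa. The labels describe the CdS dose both as 2 mM and as 20 mg per culture. In 100 mL, 20 mg of CdS comes to 1.38 mM and 2 mM to 28.9 mg, so these statements differ and no dose is used in any comparison. A general protocol gives 44 h for sampling in mid-exponential phase, while the labels of the fructose samples give 48 h. The time of the fructose samples therefore cannot be separated from their substrate. Nanoparticles, light and gas also change together between CdS with light and H2/CO2, and a culture with CdS in the dark or with light alone was not analysed here. Per the labels' protocols, total RNA was extracted with TRIzol from cells ground in liquid nitrogen and treated with DNase. Ribosomal RNA was removed with a Ribo-Zero kit, stranded TruSeq libraries were made, and 100-bp single-end reads were sequenced on an Illumina HiSeq instrument.

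The authors deposited a table of counts per locus tag, with whole numbers that were not normalised and 1 column per library. Per the submitters' processing notes DESeq2 was used, with no version. The aligner, the counting program, its strand setting and the genome build are not given in the sources used here. How reads from near-identical copies, overlapping genes or antisense transcripts were counted is therefore unknown, and values of such tags are uncertain. The reads came from PCR-amplified libraries without molecular identifiers in the labels, so counting floors cover counting error only. All columns of the table were used. The table has 4070 rows, of which 95 are at 0 in all libraries, and no tag is listed more than 1 time.

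The table does not pair locus tags with names. The gene table used for names covers RefSeq assembly GCF_001484725.1 and matched 0 of the 4070 tags under any of its identifiers. Gene lists for pathways had been fixed before the data were examined and could not be filled, so no test of a pathway is reported. For the same reason ribosomal and transfer RNA rows could not be told from other rows. The rule for named tags, also set before the data were examined, called for genes with product names and, where none could be had, for 2 tags that rose and 2 that fell in each comparison. The 2 with the largest positive and the 2 with the largest negative log2 fold change were taken. They had to have adjusted p under 0.05, a mean log2 CPM of at least 5 and no overlap between the libraries of the 2 conditions. In 91.3% of rows the tag number is 5 above that of the row before, so table order mostly follows tag number. Some late-numbered tags stand among lower-numbered ones, such as CAETHG_RS20485 at the end of a run that starts with CAETHG_RS07805. Positions on the genome were not used here.

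Libraries were grouped by the culture condition in the labels. Counts were filtered with filterByExpr by condition, which left 3362 tags, and scaled with TMM factors. All 9 libraries were fitted in 1 model with edgeR 4.0.16 in R 4.3.3, with group means and no other term (glmQLFit, glmQLFTest). The fit had 6 residual and 9.72 prior degrees of freedom and a biological coefficient of variation of 0.150. Tags with Benjamini-Hochberg adjusted p under 0.05 are called higher or lower. Normalised CPM were taken over the library total multiplied by the TMM factor. The standard error of a log2 fold change was approximated as its size divided by the square root of the F statistic. The labels do not say that the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. The labels number the replicates 1 to 3 in each condition without saying what a number stands for. Correlations of the deviations from the condition means were over 0.1 in all 3 same-number pairs of H2/CO2 and fructose (0.201, 0.165 and 0.272). The numbers may therefore pair those libraries. These correlations are low and 3 libraries per condition can be matched in few ways, so the check cannot settle it. None of the 6 same-number pairs with a CdS library was over 0.1. Simulations with no effect drew every library independently, without such pairs. Shares of counts were compared with two-sided exact permutation tests.

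Depth outside the 5 most abundant features was lowest in CdS with light, at 1295216 to 1716992 counts per library, and TMM factors were 0.431 to 0.593 there, 1.25 to 1.41 in H2/CO2 and 1.40 to 1.61 in fructose. A fold change that uses these factors is relative to the bulk of tags, and with library totals it is relative to all counts, the 5 features included. No spike-in is named in the labels, so neither scaling gives RNA per cell.

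The edgeR step was tested on simulated counts, with means and library sizes taken from the real counts and with 100 tags changed 2-fold and 100 changed 4-fold. For CdS with light against H2/CO2, with 3325 tags in the step, 72% of the 2-fold and 91% of the 4-fold changes were recovered and 2.40% of calls were false. For CdS with light against fructose, with 3327 tags, these values were 75%, 92% and 5.65%. For H2/CO2 against fructose, with 3330 tags, they were 78%, 95% and 6.49%. Few tags were changed in these simulations, while 53.7% to 66.9% of tested tags were called in the real comparisons. The share of the 5 most abundant features also ran from 21.8% to 74.9% between the real conditions. The simulations do not test scaling under differences that wide, so their recovery and false-call rates may not hold for the real calls. The search for runs of neighbouring rows recovered 10 of 10 planted runs over 4070 rows.

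Alternatives planned before the data were examined were RLE and upper-quartile factors, library totals alone, no filter beyond a count above 0, at least 50 counts in at least 3 libraries, DESeq2 1.42.0, limma-voom with limma 3.58.1, the robust edgeR fit, a test against a 1.5-fold change, fits of only the 2 conditions compared, a replicate block, the 10 most abundant rows left out, and each library left out in turn. Added after seeing the data were fits without the 5 most abundant features, with TMM factors and with library totals, a fit without 2 libraries, thinning to an equal count outside the 5 features, and a replicate block with only the H2/CO2 and fructose libraries.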

Results

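RNA abundance was measured by sequencing in *Clostridium autoethanogenum*, an anaerobic acetogenic bacterium that can grow on CO2 with H2 as electron donor or on sugars. Cultures in PETC medium, a growth medium used for acetogens, were kept under 3 conditions, with 3 libraries for each. In the first condition the cells were given nanoparticles of cadmium sulfide (CdS), a semiconductor that absorbs blue light, under a CO2 headspace and a 450 nm lamp, with no H2 named among the gases. In the second the headspace held 80% H2 and 20% CO2. In the third the medium held 5 g/L fructose under N2. The deposited table listed read counts for 4070 locus tags. Total counts per library were 4732476 to 6958630 for CdS with light, 6416695 to 6888196 for H2/CO2 and 5334968 to 7154179 for fructose. The table does not pair its locus tags with gene names, and 0 of the 4070 tags matched the gene table used here. Tags are therefore given as the table lists them, with no gene function, and gene groups are runs of neighbouring rows of the table.

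Pearson's r of log2 CPM across tags was 0.968 to 0.978 among the CdS libraries, 0.990 to 0.991 among the H2/CO2 libraries and 0.979 to 0.991 among the fructose libraries. The fructose libraries had a mean r of 0.798 to 0.828 with the CdS libraries and of 0.897 to 0.906 with the H2/CO2 libraries. The first principal component held 60.4% of the variance and the second 28.1%. No pair of replicates agreed within sampling noise, since chi-square per degree of freedom lay between 13.9 and 103 for the 9 replicate pairs.

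A few very abundant features separated the conditions at the level of whole libraries. The 5 features with the highest mean count held 74.9% ± 2.12 (SD, n = 3) of all counts in CdS with light, 41.7% ± 2.82 in H2/CO2 and 21.8% ± 4.70 in fructose. CAETHG_RS20545 held 31.2% ± 2.23 of counts in CdS with light, 13.7% ± 1.20 in H2/CO2 and 5.95% ± 1.57 in fructose. CAETHG_RS20265 held 14.5% ± 1.70 in CdS with light, 2.41% ± 0.304 in H2/CO2 and 1.42% ± 0.366 in fructose. CAETHG_RS20430, the fifth of these features, held 6.87% ± 0.900 in CdS with light, 6.84% ± 0.171 in H2/CO2 and 2.78% ± 0.652 in fructose, so its share differed between the first 2 conditions by less than the spread between replicates. Scaled with TMM factors, which set each library to the bulk of its tags, CAETHG_RS20430 was 2.70-fold higher in CdS with light than in H2/CO2 (log2 fold change 1.43 ± 0.255 SE, adjusted p = 1.30e-04 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). On the same scale CAETHG_RS20545 was 6.09-fold and CAETHG_RS20265 15.7-fold higher. For the summed share, the 3 libraries of each condition lay apart from those of every other condition (two-sided exact permutation p = 0.1 for each pair of conditions, the smallest that 3 libraries against 3 allow). The 5 features and the 3 tags named among them were chosen after their values were seen. Outside them, 1295216 to 1716992 counts per library were left for all other tags in CdS with light, 3676035 to 3953029 in H2/CO2 and 3904836 to 5901230 in fructose. The median count per table row was 24 to 36, 91 to 103 and 80 to 119, so low tags were measured with least precision in CdS with light.

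**Figure D1:**
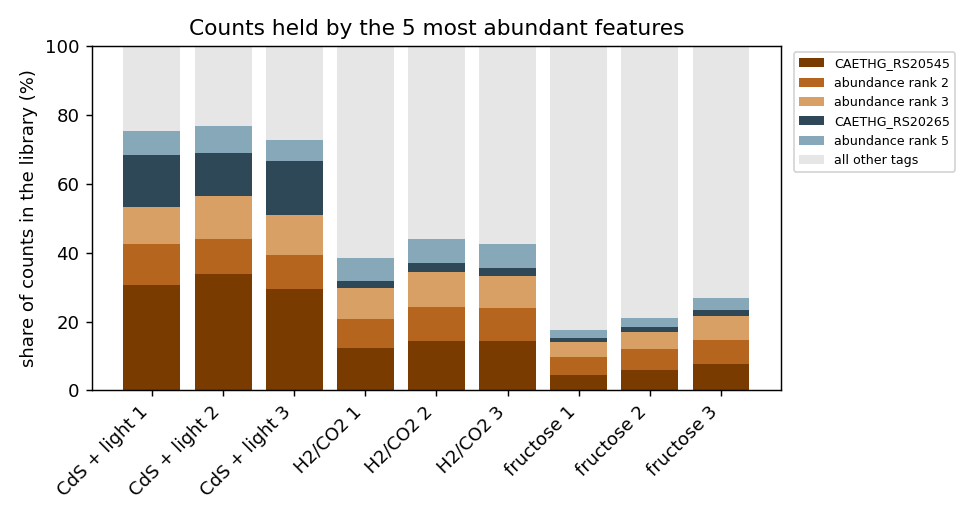
Share of counts (y axis, percent of the library's total) held by the 5 features with the highest mean count and by all other tags, in each of the 9 libraries (x axis, 3 per condition). The 5 features together hold 74.9% on average in CdS with light, 41.7% in H2/CO2 and 21.8% in fructose.

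The comparison of CdS with light against H2/CO2 asks how RNA levels differed between cultures given illuminated CdS under CO2 and cultures given H2 with CO2. CAETHG_RS09240 stood at 258 ± 35.6 normalised CPM (SD, n = 3) in CdS with light and at 1.28 ± 0.345 in H2/CO2, and CAETHG_RS09225 at 1811 ± 266 and 11.7 ± 4.04. In the other direction, CAETHG_RS00085 stood at 3.94 ± 1.06 normalised CPM in CdS with light and 405 ± 59.9 in H2/CO2, and CAETHG_RS00080 at 7.48 ± 1.1 and 590 ± 65.1. Among 3362 tested tags, 1055 were higher and 1106 lower in CdS with light than in H2/CO2 after Benjamini-Hochberg adjustment of edgeR's quasi-likelihood test, together 64.3% of the tested tags. Of these, 688 were higher and 718 lower by at least 2-fold, and 104 and 92 by at least 8-fold. The log2 fold change was 7.62 ± 0.207 (SE) for CAETHG_RS09240, 197-fold, with adjusted p = 3.70e-13 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It was 7.27 ± 0.259 for CAETHG_RS09225, -6.71 ± 0.221 for CAETHG_RS00085 and -6.31 ± 0.191 for CAETHG_RS00080. In the same test the adjusted p of these 3 tags was 2.77e-12, 1.39e-12 and 5.55e-13 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjustment). The low side of some of these folds rested on few counts per library. CAETHG_RS09240 had 8 to 15 and CAETHG_RS09225 70 to 129 in H2/CO2, and CAETHG_RS00085 had 10 to 12 and CAETHG_RS00080 18 to 24 in CdS with light. In 70.0% of the tested tags the 3 libraries of one condition did not overlap the 3 of the other in normalised CPM, where chance gives 10%. The direction of the bulk of calls rested on the scaling: with library totals in place of TMM factors, 256 tags were called higher and 2471 lower, and the median log2 fold change moved from -0.04 to -1.44. With library totals the log2 fold change of CAETHG_RS09240 was 6.22 and that of CAETHG_RS00085 -8.11, on the same sides of 0.

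CAETHG_RS09240 and CAETHG_RS09225 lay in a run of 14 neighbouring table rows, each of which was called at least 2-fold higher in CdS with light than in H2/CO2. The mean log2 fold change over the 14 tags was 4.67 ± 1.89 (SD over tags), from 1.41 to 7.62. CAETHG_RS00085 and CAETHG_RS00080 lay in a run of 10 neighbouring rows that were all lower, with a mean of -3.11 ± 2.05. These 10 tags did not behave alike against fructose: 8 were called lower and 2 higher, both in CdS with light and in H2/CO2. A further run of 13 rows was higher in CdS with light by 2.31 ± 0.73 on average, and a run of 12 rows was lower by a mean log2 fold change of -3.27 ± 1.05. With library totals as the scaling, 13 of the 14 tags of the first run and 9 of the 13 tags of the other higher run were still called higher, and 1 of these 13 had a fold change below 0. Every tag of both lower runs was still called lower. That does not test the lower runs, since library totals moved the median log2 fold change from -0.04 to -1.44.

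The comparison of CdS with light against fructose sets the illuminated CdS cultures beside cells given an organic substrate. CAETHG_RS09240 stood at 258 ± 35.6 normalised CPM (SD, n = 3) in CdS with light and 1.05 ± 0.137 in fructose, and CAETHG_RS09235 at 465 ± 63.6 and 3.28 ± 0.617. CAETHG_RS00085 stood at 3.94 ± 1.06 in CdS with light and 735 ± 40.1 in fructose, and CAETHG_RS00080 at 7.48 ± 1.1 and 1218 ± 37.8. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1023 tags were higher and 1225 lower in CdS with light, together 66.9% of those tested. By at least 2-fold, 736 were higher and 785 lower, and by at least 8-fold 129 and 75. The log2 fold changes were 7.90 ± 0.211 (SE) for CAETHG_RS09240, 7.15 ± 0.209 for CAETHG_RS09235, -7.58 ± 0.224 for CAETHG_RS00085 and -7.36 ± 0.196 for CAETHG_RS00080. Their adjusted p values in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 1.43e-13, 3.41e-13, 3.41e-13 and 1.43e-13. In fructose CAETHG_RS09240 had only 7 to 13 counts per library and CAETHG_RS09235 26 to 38. In 69.0% of tested tags the libraries of the 2 conditions did not overlap, against 10% by chance. With library totals as the scaling the split was 273 higher and 2570 lower, the median log2 fold change moved from -0.12 to -1.70, CAETHG_RS09240 stood at 6.32 and CAETHG_RS00085 at -9.16. The sample labels give 48 h for the fructose cultures and 44 h for the others, so substrate and sampling time were not separate in any comparison with fructose.

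The run of 14 rows that holds CAETHG_RS09240 was higher here as well, with a mean log2 fold change of 4.75 ± 1.97 (SD over tags) and all 14 tags called. The same 14 tags differed little between H2/CO2 and fructose, with a mean of 0.08 ± 0.49, where 2 were called higher, 2 lower and 10 were not called. A run of 8 rows with CAETHG_RS00085 and CAETHG_RS00080 was lower in CdS with light than in fructose by a mean log2 fold change of -4.96 ± 1.92. The longest run of this comparison, 16 rows, was lower by a mean of -1.93 ± 0.60, and 14 of its tags were also called lower in H2/CO2 than in fructose while 2 were called higher there. With library totals, 12 of the 14 tags of the higher run were still called higher and 1 had a fold change below 0. All 8 and all 16 tags of the lower runs were still called lower with library totals. That does not test the lower runs, since this scaling moved the median log2 fold change down to -1.70.

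CdS with light was then set against both other conditions at once. In edgeR's quasi-likelihood test 757 tags were higher in CdS with light than in H2/CO2 and than in fructose, and 806 were lower than in both. CAETHG_RS09240, CAETHG_RS09235 and CAETHG_RS09225 were among the higher tags, and CAETHG_RS00085 and CAETHG_RS00080 among the lower ones. Another 129 tags lay between the other 2 conditions, higher than one and lower than the other. Both comparisons share the CdS libraries. In 20 simulations with no effect in any condition the counts were at most 0 higher and 0 lower. Calls are rare in such draws, so the draws cannot measure the overlap that shared libraries give to lists as long as the real ones. Independent lists of these lengths would share 321 higher and 403 lower tags. Across tags, which are not independent replicates, the 2 sets of log2 fold changes had r = 0.69 against 0.64 in simulations with no effect, and a covariance of 1.82 against 0.0528. The 3 CdS libraries were not divided between the 2 comparisons, so part of the excess may come from the shared libraries. Which direction held more tags rested on the scaling and on the rows used, with 837 higher and 728 lower than in both for RLE factors, 894 and 679 for upper-quartile factors, and 156 and 2249 for library totals. The counts were 893 and 754 for DESeq2, which also differs in test and filter. They were 852 and 754 with the 10 most abundant rows left out. When a change had to exceed 1.5-fold the lower count was 491.

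**Figure D2:**
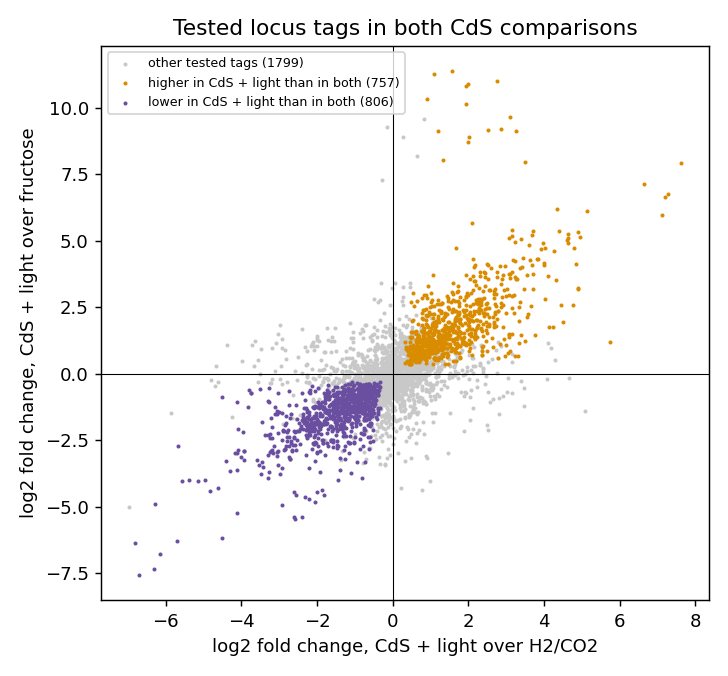
Each point is 1 of 3362 tested locus tags, with the log2 fold change of CdS with light over H2/CO2 on the x axis and over fructose on the y axis. The 757 tags called higher than in both conditions lie to the upper right, the 806 called lower than in both to the lower left, and all other tags are grey.

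The comparison of H2/CO2 against fructose sets growth on gas beside growth on sugar. CAETHG_RS04765 stood at 121 ± 63.7 normalised CPM (SD, n = 3) in H2/CO2 and 3.84 ± 0.456 in fructose, and CAETHG_RS16000 at 338 ± 67.7 and 12.2 ± 2.96. CAETHG_RS00040 stood at 121 ± 10.2 in H2/CO2 and 3899 ± 720 in fructose, and CAETHG_RS00035 at 42.2 ± 3.72 and 979 ± 89.4. Fewer tags passed than in the CdS comparisons, with 873 higher and 931 lower in H2/CO2 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, together 53.7% of those tested. By at least 2-fold, 426 were higher and 440 lower, and by at least 8-fold 75 and 40. The log2 fold changes were 4.97 ± 0.330 (SE) for CAETHG_RS04765, 4.78 ± 0.247 for CAETHG_RS16000, -5.01 ± 0.196 for CAETHG_RS00040 and -4.54 ± 0.181 for CAETHG_RS00035. Their adjusted p values in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 3.90e-09, 3.39e-10, 2.95e-11 and 2.95e-11. In 61.6% of tested tags the libraries of the 2 conditions did not overlap, against 10% by chance. The split was 627 higher and 1073 lower with library totals, and 1208 higher and 643 lower with library totals after the 5 most abundant features were left out. When a change had to exceed 1.5-fold, 443 tags were higher and 473 lower.

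CAETHG_RS16000 and CAETHG_RS04765 were higher in H2/CO2 than in CdS with light as well. For CAETHG_RS16000 the log2 fold change of CdS with light over H2/CO2 was -3.71 ± 0.244 (SE, adjusted p = 1.98e-09 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and for CAETHG_RS04765 it was -4.67 ± 0.371. CAETHG_RS04765 showed no detectable difference between CdS with light and fructose (log2 fold change 0.30 ± 0.476, adjusted p = 0.585 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Both tags lay in runs of neighbouring rows. The run of 10 rows with CAETHG_RS16000 had a mean log2 fold change of 4.37 ± 0.22 (SD over tags) in H2/CO2 over fructose, and the run of 11 rows with CAETHG_RS04765 had 3.72 ± 1.15. In CdS with light over H2/CO2 the same 10 and 11 rows had means of -3.63 ± 0.65 and -2.79 ± 1.03. CAETHG_RS00040 and CAETHG_RS00035 were lower than in fructose in both other conditions, with log2 fold changes of CdS with light over fructose of -4.02 ± 0.188 and -4.31 ± 0.183.

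**Figure D3:**
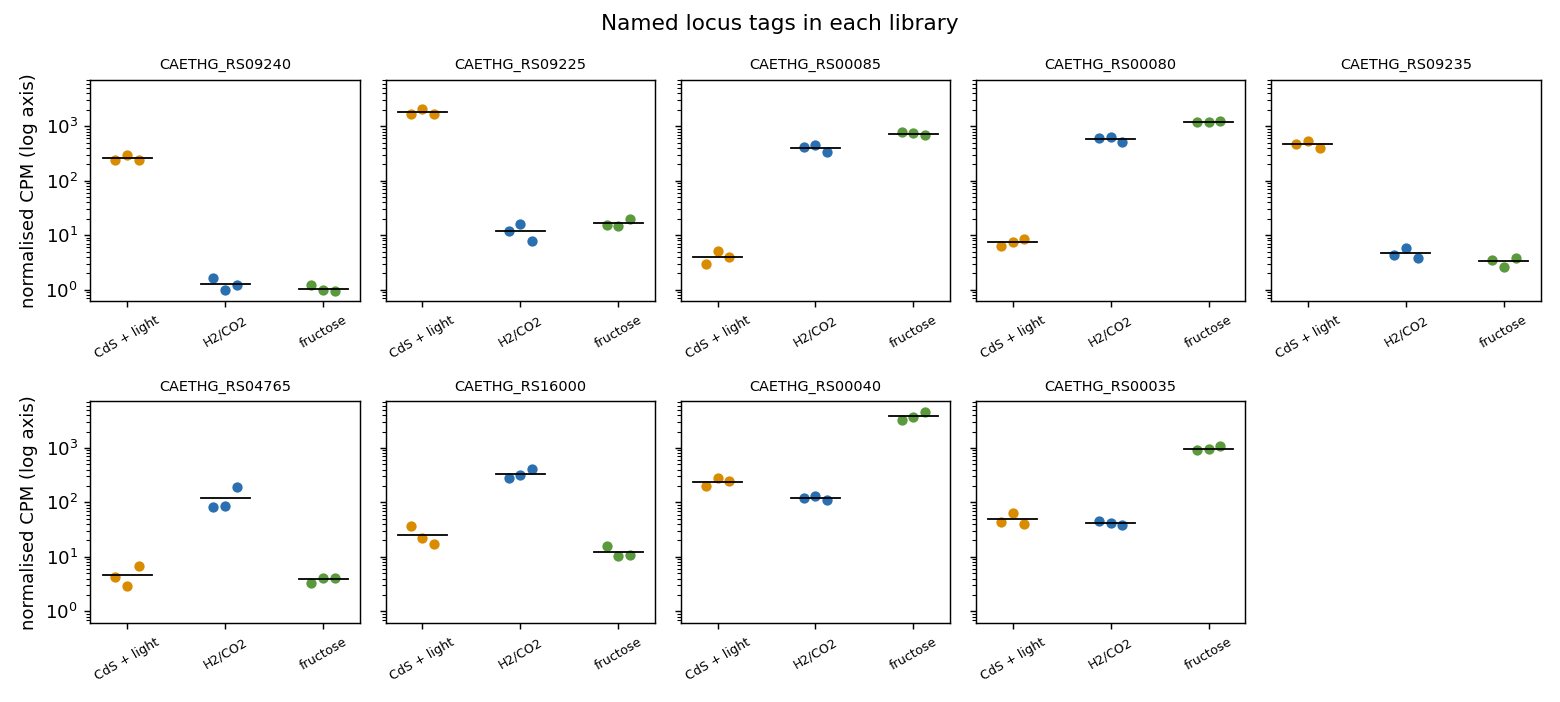
Normalised CPM on a log axis (y) for each of the 9 locus tags named in the comparisons, in the 3 libraries of each condition (x). Points are libraries and the horizontal lines are the means of 3 libraries, such as 258, 1.28 and 1.05 normalised CPM for CAETHG_RS09240 in CdS with light, H2/CO2 and fructose.

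Both CO2-fed conditions were compared with fructose together. In edgeR's quasi-likelihood test 458 tags were higher in both than in fructose and 574 were lower in both. A run of 21 neighbouring rows was lower in H2/CO2 than in fructose by a mean log2 fold change of -1.79 ± 0.38 (SD over tags), and 20 of its 21 tags were also called lower in CdS with light, with a mean of -1.94 ± 0.83. A run of 19 rows was higher in H2/CO2 than in fructose by 1.45 ± 0.26, and all 19 tags were also called higher in CdS with light, with a mean of 2.26 ± 0.66. With library totals as the scaling, the mean of these 19 tags in CdS with light over fructose was 0.67 ± 0.66, with 13 called higher, 1 lower and 5 not called, while all 19 were still called higher in H2/CO2. All 21 tags of the lower run were called lower in both with library totals. For CdS with light this does not test the run, since the median log2 fold change over fructose was then -1.70. In H2/CO2 over fructose that median was -0.20. Both comparisons share the fructose libraries. Simulations with no effect in any condition gave at most 1 shared higher and 0 shared lower tags in 20 draws. With so few calls these draws cannot measure the overlap that sharing gives to long lists. Independent lists would share 266 and 339. Across tags the fold changes had r = 0.52 against 0.42 in simulations with no effect, and a covariance of 1.16 against 0.0298. The 3 fructose libraries were not divided either, so part of the excess may come from sharing them. The balance of directions rested on the scaling here too, with 520 tags higher and 500 lower in both for RLE factors, 146 and 995 for library totals, and 587 and 415 for library totals after the 5 most abundant features were left out. When a change had to exceed 1.5-fold the counts were 223 and 273.

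Runs of neighbouring rows were more frequent than chance order gives in all 3 comparisons. A run was at least 5 consecutive table rows, each called in the same direction and changed at least 2-fold. This rule was set after the data had been seen. CdS with light against H2/CO2 had 27 runs, 12 higher and 15 lower, which held 13.2% of the tags changed at least 2-fold. CdS with light against fructose had 33 runs, 14 higher and 19 lower, with 16.0% of such tags. H2/CO2 against fructose had 26 runs, 10 higher and 16 lower, with 23.8%. When the calls were shuffled over the tested rows 1000 times, the mean number of runs was 1.39, 2.00 and 0.139 in the same order (one-sided permutation p = 0.001 for each, the smallest that 1000 shuffles can give). The number of runs was 139 in CdS with light against H2/CO2 and 153 in CdS with light against fructose with library totals as the scaling, and 15 in the first of these when only tags with at least 50 counts in at least 3 libraries were tested. Shuffles were not repeated for these settings. With library totals 2280 and 2476 tags were changed at least 2-fold, against 1406 and 1521 with TMM factors, so chance order alone gives more runs there.

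**Figure D4:**
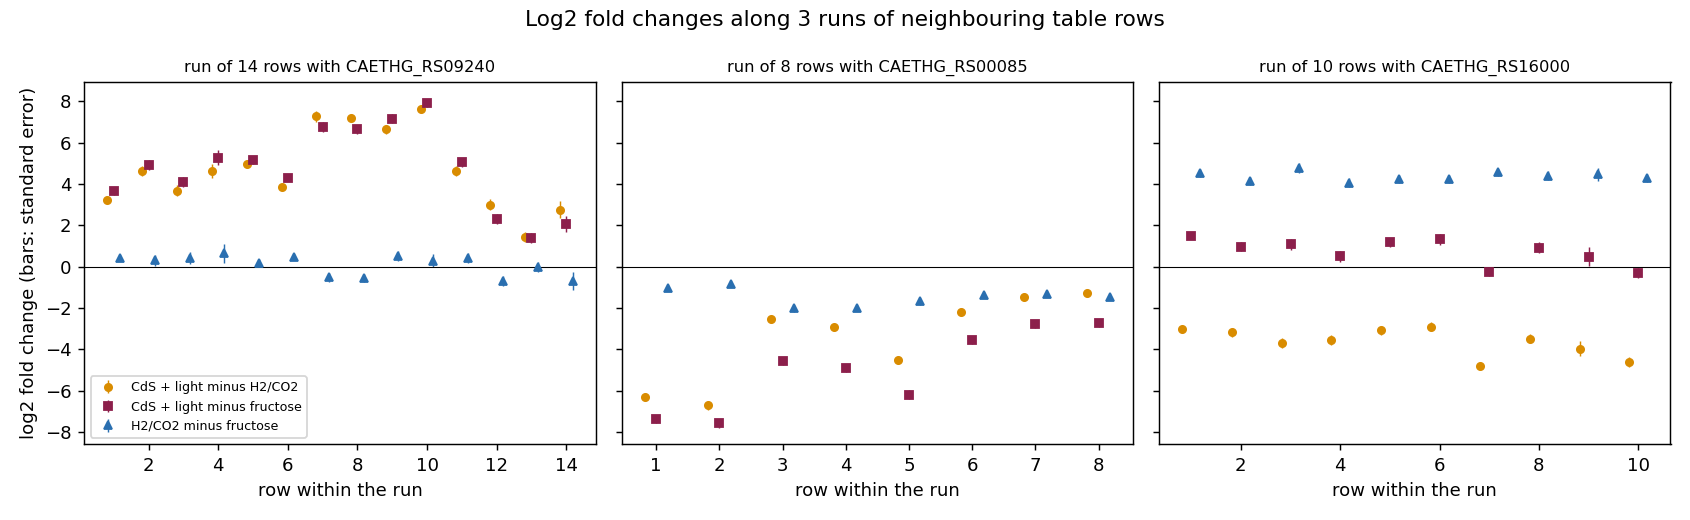
Log2 fold change (y axis) of each tag along 3 runs of neighbouring table rows (x axis, row within the run), for the 3 comparisons, with bars for the standard error. The run of 14 rows is higher in CdS with light in both of its comparisons (means 4.67 and 4.75), the run of 8 rows is lower in CdS with light than in fructose (mean -4.96), and the run of 10 rows is higher in H2/CO2 than in fructose (mean 4.37) and lower in CdS with light than in H2/CO2 (mean -3.63).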

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

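The 285 tags below were singled out because their differences from fructose went in opposite directions in the other 2 conditions. This pattern was looked for only after the calls were known. Of the 285 tags, 105 were higher in CdS with light and lower in H2/CO2 than in fructose, and 180 were lower in CdS with light and higher in H2/CO2, each call by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The difference between CdS with light and H2/CO2 was past the threshold of that test for all 285 tags, which their choice makes nearly certain, since that difference is the sum of 2 called differences. Simulations with no effect in any condition gave 0 such tags in 20 draws. Calls are rare in such draws, so this says little about lists as long as the real ones. Independent lists as long as the real ones would share 283 tags of the first kind and 318 of the second, so opposite calls were fewer than independent lists give, and both comparisons share the fructose libraries. When a change had to exceed 1.5-fold, 68 tags showed opposite calls, and over the other settings tried the count ran from 204 with counts thinned to the shallowest library to 354 with library totals. No technical explanation for these tags was weighed.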

How the results depend on the processing

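Named tags were chosen for the largest changes in these same counts, so refits were nearly certain to keep them. All 12 fold changes of named tags kept their direction and stayed past the threshold in each of the 25 or 26 alternative settings run for them. Their ranges in CdS with light over H2/CO2 were 6.22 to 7.83 for CAETHG_RS09240 and -8.11 to -6.51 for CAETHG_RS00085. For the main counts, 355 alternative values lay within 1.5 times the reported ones and 17 did not, and for named tags, 2-fold counts, runs and opposite calls 474 held and 6 moved. With library totals, CdS with light over H2/CO2 had 256 higher and 2471 lower tags, and over fructose 273 and 2570. Against both it had 2405 tags, 156 higher and 2249 lower, and both CO2-fed conditions had 146 higher and 995 lower than fructose. The 2-fold counts then were 2280 and 2476 in the CdS comparisons. Library totals include the 5 most abundant features, and without these features library totals gave 2220, 2284 and 1851 calls in the 3 comparisons. In the CdS comparisons these were 949 higher and 1271 lower, and 1120 and 1164, much nearer to the splits with TMM factors. In H2/CO2 over fructose they were 1208 and 643, against 873 and 931 with TMM factors. The 5 features therefore do not account for all of the dependence on scaling. When a change had to exceed 1.5-fold, H2/CO2 against fructose had 916 calls (443 higher, 473 lower), CdS with light against both 1004 (491 lower) and the CO2-fed conditions together 496 (223 higher, 273 lower), since small changes then do not pass. Other settings moved the median log2 fold change by over 0.1 as well. In CdS with light over H2/CO2 it went from -0.04 to 0.14 with upper-quartile factors, 0.11 with DESeq2, 0.06 with thinned counts and -0.18 with library totals without the 5 features, which also moved it to 0.23 in H2/CO2 over fructose. In CdS with light over fructose it went from -0.12 to between -0.02 and 0.09 with RLE, upper-quartile factors, DESeq2, thinned counts, the 10 most abundant rows left out, and library totals without the 5 features. The majority of calls, lower in all 3 comparisons in the main fit with TMM factors, turned to higher in CdS with light over fructose with RLE (1149 higher, 1108 lower), upper-quartile factors (1163, 1094) and DESeq2 (1203, 1130). It also turned in CdS with light over H2/CO2 (1115, 1057; 1256, 967; 1207, 1077 in the same order). In H2/CO2 over fructose it turned with RLE (946, 847) and DESeq2 (894, 799), not with upper-quartile factors (820, 985). Leaving out each library in turn gave 1994 to 2289, 2070 to 2321 and 1559 to 1853 calls, with 5 to 270 calls lost and 0 reversed. Settings added after seeing the data gave 2250, 2303 and 1869 calls without CdS library 2, which had the most rows at 0, and fructose library 3, which had the highest share in the 5 features among its group. Thinning all libraries to 1295216 counts outside the 5 features gave 1947, 1978 and 1480, of which 1821, 1864 and 1440 were also called at full depth, so depth limits part of the calls. DESeq2 gave 2284, 2333 and 1693 calls, sharing 2095, 2128 and 1635 in the same direction and 0 in the opposite one. A replicate block gave 2171, 2250 and 1845 calls, of which 2143, 2226 and 1788 were shared in the same direction, 0 in the opposite one. A block fitted to the H2/CO2 and fructose libraries alone, added after seeing the data, gave 1934 calls with 1786 shared. No named call was lost under either block. The 6 same-number pairs with a CdS library had correlations of -0.11 to 0.03, so this check shows no pairing of these, and 2 of 9 libraries correlated best with their own number in both other conditions. Not run were the fits without ribosomal and transfer RNA rows and all tests of gene lists with their alternatives, since the tags could not be matched to names.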

Other observations

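The calls of the 3 comparisons come from fits planned before the data were examined, while the tests of explanations, the counts of runs and of tags at 0 and the counts of tags with H2/CO2 highest or lowest were chosen after the results had been seen. H2/CO2 also stood apart from the other 2 conditions. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 429 tags were higher in H2/CO2 than in both CdS with light and fructose, and 342 were lower than in both. CAETHG_RS16000, at 338 ± 67.7 normalised CPM (SD, n = 3) in H2/CO2, 25.5 ± 9.84 in CdS with light and 12.2 ± 2.96 in fructose, was among the higher ones. In a run of 10 neighbouring rows without a named tag, the mean log2 fold change was -2.62 ± 0.91 (SD over tags) in CdS with light over H2/CO2 and 2.51 ± 1.38 in H2/CO2 over fructose, where 8 of its tags were called. At the other end, 515 of the 3362 tested tags were called in no comparison and 878 in all 3.

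The first pattern weighed is the rise of the 5 most abundant features from 21.8% of counts in fructose to 41.7% in H2/CO2 and 74.9% in CdS with light. Dilution of all other tags is argued against as the whole cause of the calls between H2/CO2 and CdS with light, because 1491 tags were still called and changed at least 2-fold with the 5 features left out and library totals for the rest. An added source of RNA with these features in a fixed ratio stays open: relative to all other tags each of the 5 rose from H2/CO2 to CdS with light, by 2.35-fold for CAETHG_RS20430 to 13.9-fold for CAETHG_RS20265, and since the make-up of such a source is unknown, unequal rises do not decide. A difference in ribosomal RNA removal or RNA integrity cannot be told apart from a difference in the cells, since 0 tags matched the gene table and the kind of RNA of these features is unknown. The culture condition itself also stays open, as untested.

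The second pattern concerns tags at 0 in fructose. Of 2701 tags with at least 100 summed counts in H2/CO2, 11 had 0 counts in all 3 fructose libraries and 2 had 1 to 10, while in CdS with light 0 were at 0 and 31 at 1 to 10. The 11 tags had 112 to 539 summed counts in H2/CO2 and 74 to 411 in CdS with light, were counted in all 6 of those libraries, and were at least 40.2- to 194-fold higher in H2/CO2 with a floor of 3 counts over the fructose libraries. Graded low expression is argued against by 11 tags at 0 beside 2 at 1 to 10, and loss of 1 stretch of the genome by 660 of the 703 table rows between the first and last of these tags having counts in fructose. Different handling or counting of the 3 fructose libraries, or a different stock of cells, cannot be told apart from the fructose condition, since every fructose library shares both.

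The third pattern is the runs of neighbouring rows. Chance order is argued against, because the highest number of runs in 1000 shuffles was 6, 7 and 2 where 27, 33 and 26 were seen. Across pairs of tested tags the correlation of log2 fold changes was 0.40, 0.41 and 0.50 at a distance of 1 row and -0.02, -0.03 and -0.02 at 50 rows. Bacterial genes that lie side by side are often transcribed together, and a candidate explanation is that these runs are such units. That hypothesis was not tested, since positions and strands of the tags were not used here, and reads counted into more than 1 neighbouring tag remain open as well.

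Other divisions of the libraries bear on the counts of calls. For CdS with light against H2/CO2, CdS with light against fructose and H2/CO2 against fructose, the real division gave 2161, 2248 and 1804 calls and was in each case 1 of 10 divisions with a count as large. The highest count of any other division was 0 in each by edgeR's quasi-likelihood test, with at most 72, 140 and 137 tags at an unadjusted p under 0.05 against 2262, 2334 and 1954 in the real division, and 10 divisions are too few for a share under 0.05. Every other division mixed the 2 conditions within its groups, which widens their spread and lowers the count. Counts near 0 were therefore nearly certain there and say little about the real calls. For H2/CO2 against fructose, where the numbers may pair the libraries, 4 of the 10 divisions part all 3 same-number pairs, and apart from the real one these gave at most 37 tags at an unadjusted p under 0.05. For tags changed in CdS with light against both other conditions, 1 of 100 drawn divisions, the real one, reached 1563, and the highest other count was 431. That highest count came from a draw that split the CdS libraries over groups. Groups that mix conditions have a wider spread, which lowers the count. The share therefore argues only against no grouping of the 9 libraries at all. None of the other drawn divisions kept the CdS libraries together in their own place. When they were kept there and the other 6 libraries were divided in all 10 ways, the real division gave 1563 and the others 1207 to 1239. Whether the same tags were called was not checked. These totals therefore do not show how far the 1563 tags rest on telling H2/CO2 from fructose, and 10 divisions are too few for a share under 0.05. For tags shared by both CO2-fed conditions against fructose, 2 of 100 divisions reached 1032. The other one, with 1207, kept the 3 CdS libraries together in the place of fructose. This share too argues only against no grouping of the 9 libraries at all. Neither set of draws takes account of the same-number pairs of H2/CO2 and fructose. The second count does not single out the real grouping of the CO2-fed conditions, since that other division gave more, which points to a structure of the samples in which the CdS libraries stand together.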
